A study of Mus musculus and Homo sapiens with 33 samples.

How the data were processed

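The series holds bulk RNA-seq of sorted cells, made with a Smart-Seq protocol and Nextera XT libraries per the labels' protocols. This chemistry keeps no strand, and no molecular identifiers are described. Counts per gene were used as deposited: per the submitters' processing notes, reads were handled with CASAVA 1.8 and Trim Galore 0.4.3, aligned with STAR 2.5.2b to the mm10 and hg38 builds and counted with HTSeq. The same notes name DESeq2 1.22 and R 3.5, and the role of each tool beyond its usual one is not given in the sources used here. The values are whole numbers whose totals differ between libraries, with 24411 genes for the mouse cells and 26475 for the human tumor cells. Pairs of libraries of a group differed by far more than sampling noise, with a chi-square per degree of freedom of 13.61 to 220.6 over genes, as separate mice would. Each library was counted as 1 replicate because the labels give it a mouse of its own within its group.

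Each column was matched to its group and mouse number by name, with 0 columns left over. A replicate is a mouse, and the same number in MG, MDM, MONO and tumor libraries names the same mouse in the labels. These numbers therefore pair the samples. Deviations from the group means correlated between the MG library and the MDM or MONO library of a mouse at -0.0858 to 0.49, over 0.1 in 9 of 12 pairs, and for 10 of 12 the best match was the same mouse. The main test has no term for the mouse, and fits with mouse as a fixed or random replicate block were run beside it. The fixed block was fitted in edgeR. The random block was fitted in limma voom with a within-mouse correlation of 0.409, so it changed the test as well as the pairing. In MDM against MG with vehicle the fixed block raised the count from 3661 to 5588 genes. MONO is used as the labels give it, without further definition, and no batch or date is given in the labels used here.

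The main test was edgeR 4.0.16 in R 4.3.3 (glmQLFit and glmQLFTest, two-sided) on the deposited counts, with TMM scaling, filterByExpr by group and Benjamini-Hochberg adjustment at a threshold of 0.05. All 24 mouse libraries entered 1 fit with a mean per group, so that groups of 3 share the spread of the others, and the 9 tumor libraries entered another. After filtering 14023 mouse and 14007 human genes were tested. Levels are TMM-normalised CPM, computed here. Log2 changes are those of edgeR, with SE derived from its test statistic, and depend on its prior count for genes near 0. Interactions were tested as differences of differences. Effects sharing the same vehicle libraries were compared with 20 simulated sets of unchanged groups and with the vehicle libraries split between the comparisons.

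The comparisons, alternatives, rule for named genes and gene lists (33 for mouse and 22 for human cells, including markers of other cell types) were chosen before the data were examined. Lists of at least 5 measured members were tested with camera of limma 3.58.1 at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison. An estimated correlation and fry were the alternatives. Members called are counted over all genes and adjusted over the list alone. List scores are means of log2 CPM with a prior count of 2.

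Genes were named by a rule. Between groups it takes the 8 genes with the highest and the 8 with the lowest log2 change among those with adjusted p under 0.05, an average log2 CPM of at least 4 and no overlap between the groups, predicted genes and clones left out. In the interaction tests it takes 6 each way without the condition on overlap. It adds up to 4 members with the smallest adjusted p of each list reported, and the genes of Csf1, Csf2 and Il34, their receptors, Stat5 and a few microglial markers in every comparison. The text names fewer, in the order of the rule. Genes outside it are said to be chosen after their values were seen.

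The alternatives were DESeq2 size factors, no filter on low counts, the DESeq2 1.42.0 Wald test, limma voom with sample quality weights, fits of the compared groups alone, the replicate blocks, and leaving out each library in turn. Fits without mouse 66277, and fits with the numbers of MONO 66941 and 66942 exchanged, were added after seeing the data. Adjusted p-values that DESeq2 gave as missing were kept as missing. Up to 100 splits of the libraries or mice, the real one included, were refitted for each comparison.

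The procedure was tested on simulated data, with counts drawn from the means, spreads and library sizes of the real groups and 200 genes changed 2-fold or 4-fold. For MG with vehicle against health it recovered 40.2% of 2-fold and 76.5% of 4-fold changes over 13774 genes, and for BLZ against vehicle in MG 37.4% and 70.4% over 13769 genes. For MDM under BLZ the shares were 51% and 72.7% over 13789 genes, for MDM against MG with vehicle 55.6% and 80% over 13783, for the BLZ interaction 17.3% and 62% over 13761, and for tumor cells 71.9% and 96% over 13767. False calls made up 5.36% (MG under BLZ) to 16.7% (MDM against MG with vehicle) of the calls.

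Total counts per library ranged from 16044037 to 20290855 in BLZ MDM, 15460961 to 19268530 in vehicle MDM, 15753915 to 19083369 in BLZ MG, 13146350 to 19156814 in vehicle MG, 17099669 to 20515079 in healthy MG and 15231828 to 16961594 in MONO. In tumor cells they ranged from 15067214 to 19881323 with BLZ and from 14527529 to 17348718 with vehicle. Reads without molecular identifiers are not independent molecules, so these totals limit counting error only, and the spread between mice is what the tests use. Because the libraries keep no strand, a gene cannot be told from an overlapping gene on the other strand, and paralogs such as Csf2rb and Csf2rb2 are uncertain. Positions come from GENCODE M21 for mm10, in which 23334 of 24411 mouse symbols matched 1 gene (95.6%). Positions of human genes and mouse reads in tumor libraries were not analysed here. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.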

Results

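RNA-seq was carried out on cells sorted from the brains of nude mice that carried metastases of MDA-BrM, a GFP-labelled human breast cancer line that grows in the brain after injection into the heart. Cells of healthy mice were sequenced as well. Mice with metastases received BLZ945 (here BLZ), a small-molecule inhibitor of the Csf1 receptor kinase Csf1r, at 200 mg per kg each day, or its vehicle, until symptoms appeared. From each of 9 such mice (5 vehicle, 4 BLZ), microglia (MG, sorted without Cd49d), monocyte-derived macrophages (MDM, sorted with Cd49d) and tumor cells were sequenced. From 3 healthy mice, MG and a population labelled MONO, whose tissue and gate the labels do not give, were sequenced. There were 33 libraries in all, 1 for each mouse and cell type. Total counts ranged from 13146350 to 20515079 in the 24 mouse libraries, with 13868 to 16387 genes detected. In the 9 tumor libraries they ranged from 14527529 to 19881323, with 16428 to 18403 genes detected. Levels are given as mean CPM ± SD over mice and log2 changes with their SE. Adjusted p-values are from edgeR's two-sided quasi-likelihood test with Benjamini-Hochberg adjustment over 14023 mouse or 14007 human genes. Gene positions are those of GENCODE M21 on the mm10 build.

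Transcripts of the sorting antigens differed between the populations. Itga4, which encodes Cd49d, was at 2.327 ± 0.295 CPM in healthy MG (n = 3), 12.13 ± 5.36 in vehicle MG (n = 5) and 21.76 ± 11.4 in BLZ MG (n = 4). It was at 100.5 ± 30.1 CPM in vehicle MDM (n = 5), 95.64 ± 14.9 in BLZ MDM (n = 4) and 581 ± 75.2 in MONO (n = 3). Vehicle MDM 66278 held 154 CPM of Itga4 and the other 4 vehicle MDM libraries 83.2 to 92. In vehicle mice Itga4 was higher in MDM than in MG (log2 change 3.05 ± 0.303, adjusted p = 1.59e-07), and in MG it was higher with metastases than in health (2.38 ± 0.4, adjusted p = 0.000387). Itgam, which encodes Cd11b, was detected in all 6 mouse groups, from 755.3 ± 313 CPM in BLZ MDM to 2079 ± 425 in vehicle MG. Ptprc, which encodes Cd45, ranged from 352.7 ± 38 CPM in healthy MG to 2123 ± 138 in MONO. In a principal component analysis the libraries of BLZ mouse 66277 stood apart. On the third component its MG and MDM lay at -70.54 and -56.99 and the other 22 mouse libraries between -33.34 and 42.76. On the first component of the tumor libraries its tumor cells lay at 70.31 and the other 8 between -21.51 and 9.703.

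The first question was how MG from brains with metastases differed from healthy MG. With vehicle, MG expressed Fn1, which encodes fibronectin, at 1241 ± 694 CPM (SD, n = 5) against 7.22 ± 0.934 in healthy MG (n = 3), a log2 change of 7.42 ± 1.12 (adjusted p = 0.000132). Fn1 lies on chromosome 1 from 71585520 to 71653200. It also varied within the metastasis groups, at 40.8 CPM in MG and 132 CPM in MDM of BLZ mouse 66277 and at 508 CPM or more in both cell types of the other 8 mice. The complement gene C4b (chromosome 17, 34728380 to 34743882) rose by 6.94 ± 1.24 on the log2 scale (adjusted p = 0.00071). The chemokine gene Cxcl13 (chromosome 5, 95956951 to 95961068) rose by 6.80 ± 1.45 (adjusted p = 0.0028). Spp1, which encodes osteopontin (chromosome 5, 104435118 to 104441050), went from 58.14 ± 11.6 to 4892 ± 2130 CPM (6.39 ± 0.79, adjusted p = 1.69e-05). Gpr165 (chromosome X, 96713441 to 96719388) had a log2 change of -3.70 ± 0.763 (adjusted p = 0.00204), and Klhdc8b (chromosome 9, 108447636 to 108461581) one of -3.67 ± 0.456 (adjusted p = 1.84e-05). In total 1222 genes were higher and 829 lower in vehicle MG. Without healthy MG 66942 the log2 change of C4b was 8.92 and that of Cxcl13 9.91. Without vehicle MG 66278 that of Cxcl13 was 5.93, and without vehicle MG 66273 that of Gpr165 was -4.39. The count of 2051 was 1080 without healthy MG 66941 and 1109 without healthy MG 66943. Limma voom called 4157 genes.

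Among gene lists fixed before the data were examined, 20 of 30 genes of disease-associated microglia rose (24 adjusted over the list alone). Their camera adjusted p was 1.12e-19, with adjusted p = 0.0242 with an estimated correlation. They included Lilrb4a (log2 change 3.85 ± 0.397) and the lipid carrier gene Apoe (chromosome 7, 19696109 to 19699188). Apoe went from 947.5 ± 393 to 37390 ± 13900 CPM (5.30 ± 0.599, adjusted p = 5.68e-06). Of the 24 homeostatic microglia genes 11 fell (13 adjusted over the list alone). Camera gave an adjusted p of 3.9e-08 (adjusted p = 0.232 with an estimated correlation). The purinergic receptor gene P2ry12 (chromosome 3, 59216272 to 59262871) was at 1503 ± 332 CPM against 5304 ± 715 (-1.82 ± 0.308, adjusted p = 0.000414), and P2ry13 fell by 1.66 ± 0.305 on the log2 scale. Tmem119, another microglial marker (chromosome 5, 113793729 to 113800516), was at 2216 ± 812 against 4173 ± 576 CPM (-0.91 ± 0.381, adjusted p = 0.115). It passed with limma voom (0.0153, range over alternatives 0.0153 to 0.298). The lysosome list rose (14 of 30 higher, 16 adjusted over the list alone; camera adjusted p = 5.38e-13, adjusted p = 0.0262 with an estimated correlation). Lipid uptake and efflux genes rose as well (12 of 25 higher and 1 lower, 15 and 1 adjusted over the list alone). For them the camera adjusted p was 2.49e-07 (adjusted p = 0.0262 with an estimated correlation). The scavenger receptor gene Msr1 (chromosome 8, 39581685 to 39642673) went from 3.692 ± 1.08 to 207.3 ± 74.2 CPM (5.81 ± 0.557, adjusted p = 7.53e-07). The lipid droplet gene Plin2 rose by 2.19 ± 0.227 on the log2 scale.

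In the same comparison 26 of 31 genes of the type I interferon response were higher in vehicle MG (28 adjusted over the list alone). Camera called the list at an adjusted p of 9.94e-15, lost at adjusted p = 0.272 with an estimated correlation. Rsad2, an antiviral enzyme gene, rose by 4.81 ± 0.819 on the log2 scale (adjusted p = 0.000429), and Oas2 by 4.13 ± 0.717. Rsad2 lost the call with mouse as a random block (0.0609, range over alternatives 2.23e-11 to 0.0609). Of 30 genes of G2/M and mitosis 28 were higher (28 adjusted over the list alone; camera adjusted p = 3.32e-13, adjusted p = 0.272 with an estimated correlation). Mki67, which encodes the proliferation antigen Ki-67 (chromosome 7, 135689784 to 135716361), was at 38.34 ± 26.2 against 7.213 ± 2.28 CPM (2.40 ± 0.468, adjusted p = 0.00138). Markers of border-associated macrophages, another brain macrophage type, were also higher (7 of 15, 7 adjusted over the list alone). The camera adjusted p of these markers was 0.00162 (adjusted p = 0.312 with an estimated correlation). Siglec1 among them rose by 5.34 ± 0.697. Without healthy MG 66942 the changes of Rsad2, Oas2 and Siglec1 were 6.28, 5.3 and 6.24. Of 23 dissociation and immediate early genes 3 were lower (3 adjusted over the list alone; camera adjusted p = 0.00162, adjusted p = 0.333 with an estimated correlation).

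Because the study concerns Csf1r inhibition and Csf2 signalling, the receptor genes were followed across the comparisons. In vehicle against healthy MG both Csf2 receptor genes rose, and with them Csf2rb2, which in the mouse encodes the beta subunit of the Il3 receptor. Csf2ra (chromosome 19, 61223957 to 61228429) was at 216.6 ± 28 against 75.28 ± 3.77 CPM (1.52 ± 0.227, adjusted p = 0.000119). Csf2rb (chromosome 15, 78325752 to 78353847) was at 444.3 ± 65.6 against 140.4 ± 21.8 CPM (1.66 ± 0.153, adjusted p = 6.45e-07). Csf2rb2 (chromosome 15, 78282507 to 78305721) rose by 1.75 ± 0.179 (adjusted p = 1.55e-06). Csf2rb and Csf2rb2 are near-identical neighbours, so the division of reads between them is uncertain. Csf1r (chromosome 18, 61100598 to 61132149) was at 11660 ± 2240 against 13960 ± 1330 CPM and did not pass the test (-0.26 ± 0.254, adjusted p = 0.54). Of 24 genes of the Csf2 receptor and Stat5 axis 8 were higher and 1 lower (8 and 2 adjusted over the list alone; camera adjusted p = 0.00697, adjusted p = 0.272 with an estimated correlation).

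**Figure D1:**
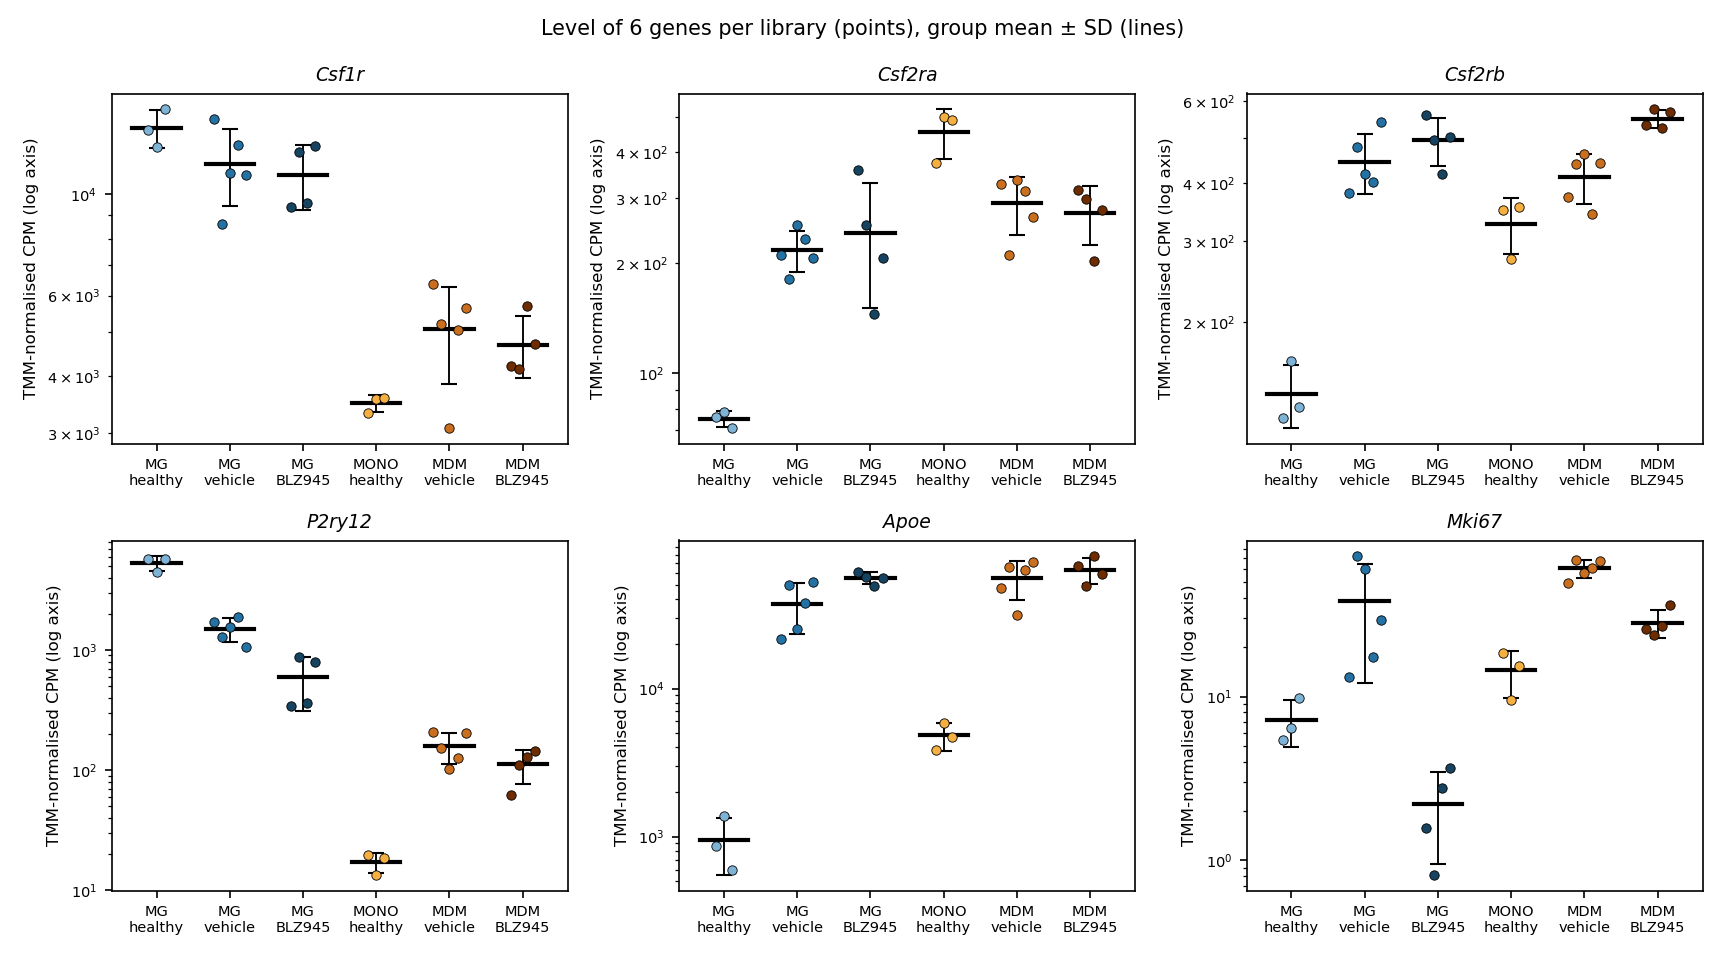
TMM-normalised CPM on a log axis of 6 genes in the 6 mouse groups, with a point per library and lines for the group mean ± SD. Csf2rb stood at 140.4 ± 21.8 CPM in healthy MG and 444.3 ± 65.6 in vehicle MG, P2ry12 fell from 5304 ± 715 to 1503 ± 332 CPM between these groups, and Mki67 was at 2.211 ± 1.26 CPM in BLZ MG.

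The next question was what BLZ changed in MG. Mki67 was at 2.211 ± 1.26 CPM (n = 4) with BLZ against 38.34 ± 26.2 (n = 5) with vehicle (log2 change -4.10 ± 0.476, adjusted p = 0.000258). The mitotic ubiquitin-conjugating enzyme gene Ube2c was at 0.4376 ± 0.398 against 11.24 ± 7.17 CPM (-4.63 ± 0.697, adjusted p = 0.00248; 0.0546 with limma voom, range over alternatives 1.34e-10 to 0.0546). The fructose transporter gene Slc2a5 (chromosome 4, 150119283 to 150144169) was at 4.703 ± 3.89 against 78.59 ± 45.9 CPM (-4.05 ± 0.605, adjusted p = 0.00139). The MAP kinase phosphatase gene Dusp7 (chromosome 9, 106368632 to 106375724) was at 11.13 ± 3.73 against 32.1 ± 2.81 CPM (-1.52 ± 0.252, adjusted p = 0.00526). The transcription factor gene Myc (chromosome 15, 61985391 to 61990374) was at 35.45 ± 10.3 against 89.88 ± 24.7 CPM (-1.34 ± 0.258, adjusted p = 0.01). Higher with BLZ was the kinase gene Cdk18 (chromosome 1, 132112237 to 132139684), at 44.39 ± 8.48 against 13.15 ± 5.2 CPM (1.75 ± 0.304, adjusted p = 0.00589). Pttg1 rose by 1.40 ± 0.289 (adjusted p = 0.0176). Socs6, a suppressor of cytokine signalling gene (chromosome 18, 88665224 to 88927481), was at 202.8 ± 79.9 against 80.42 ± 12.1 CPM (1.33 ± 0.213, adjusted p = 0.00419). With the compared groups alone, Slc2a5 (0.0572, range 3.16e-05 to 0.0572), Myc (0.0644, range 0.000133 to 0.0644) and Socs6 (0.0718, range 4.35e-06 to 0.0718) lost the call. Pttg1 lost it there too (0.0997, range 0.000752 to 0.0997) and without BLZ MG 66270 (0.0759) or 66271 (0.0754).

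In total 28 genes were higher and 101 lower in BLZ MG. Of 30 genes of G2/M and mitosis 25 fell, with a median log2 change of -2.65 (30 adjusted over the list alone). Without mouse 66277 20 fell, and without single libraries 16 (vehicle MG 66276), 15 (vehicle MG 66278), 14 (BLZ MG 66270) and 15 (BLZ MG 66277) fell, with the median between -2.8 and -2.4 without any 1 library. Camera gave this list an adjusted p of 1.15e-40 (adjusted p = 0.13 with an estimated correlation). Of the 24 homeostatic genes 3 fell, Slc2a5, P2ry12 and Crybb1, with a list median of -0.707 (10 adjusted over the list alone; camera adjusted p = 4.74e-13, adjusted p = 0.13 with an estimated correlation). Without mouse 66277 1 fell (6 over the list alone). P2ry12 went from 1503 ± 332 to 595.8 ± 284 CPM (-1.33 ± 0.299, adjusted p = 0.0292). It lost the call without vehicle MG 66276 (0.0502), 66278 (0.0676) or 66279 (0.0659), BLZ MG 66270 (0.114) or 66277 (0.108), or mouse 66277 (0.0993), within a range of 0.000756 to 0.162. Crybb1 (-1.60 ± 0.383, adjusted p = 0.045) lost it without any 1 of the libraries except vehicle MG 66370 (0.0604 to 0.115) and without mouse 66277 (0.0903; range over all alternatives 0.00781 to 0.191). The ligand gene Tnfsf9 (-2.67 ± 0.562, adjusted p = 0.0199) lost it without vehicle MG 66279 (0.0523), BLZ MG 66271 (0.0704) or 66277 (0.0853), or mouse 66277 (0.0663), with limma voom (0.0737) and with mouse as a random block (0.106), within a range of 0.00035 to 0.146. With the compared groups alone P2ry12 (0.162), Crybb1 (0.191) and Tnfsf9 (0.146) lost it as well. Neuron markers moved in the same direction in these libraries, with 0 of 14 called over all genes, 1 lower adjusted over the list alone and a median of -0.795. Their camera adjusted p was 0.00217 (adjusted p = 0.581 with an estimated correlation). Endothelial and mural cell markers had 0 of 19 called, 0 adjusted over the list alone and a median of -0.531 (camera adjusted p = 0.0241, adjusted p = 0.72 with an estimated correlation; 0.16 and a median of -0.272 without mouse 66277). The count of 129 was 72 without vehicle MG 66276, 75 without 66278, 67 without BLZ MG 66270 and 75 without 66277. It was 113 without mouse 66277, 313 with DESeq2, 44 with limma voom, 25 with the compared groups alone and 54 with mouse as a random block.

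The receptor genes in MG did not pass the test between BLZ and vehicle. Csf1r was at 11030 ± 1780 against 11660 ± 2240 CPM (-0.08 ± 0.235, adjusted p = 0.939). Csf2ra was at 240.5 ± 89.6 against 216.6 ± 28 CPM (0.15 ± 0.196, adjusted p = 0.844) and Csf2rb at 494.5 ± 58.6 against 444.3 ± 65.6 CPM (0.15 ± 0.131, adjusted p = 0.724). Apoe (0.58 ± 0.418, adjusted p = 0.665), Trem2 (-0.30 ± 0.224, adjusted p = 0.672) and Tmem119 (1071 ± 566 against 2216 ± 812 CPM, -1.05 ± 0.365, adjusted p = 0.227) did not pass either.

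**Figure D2:**
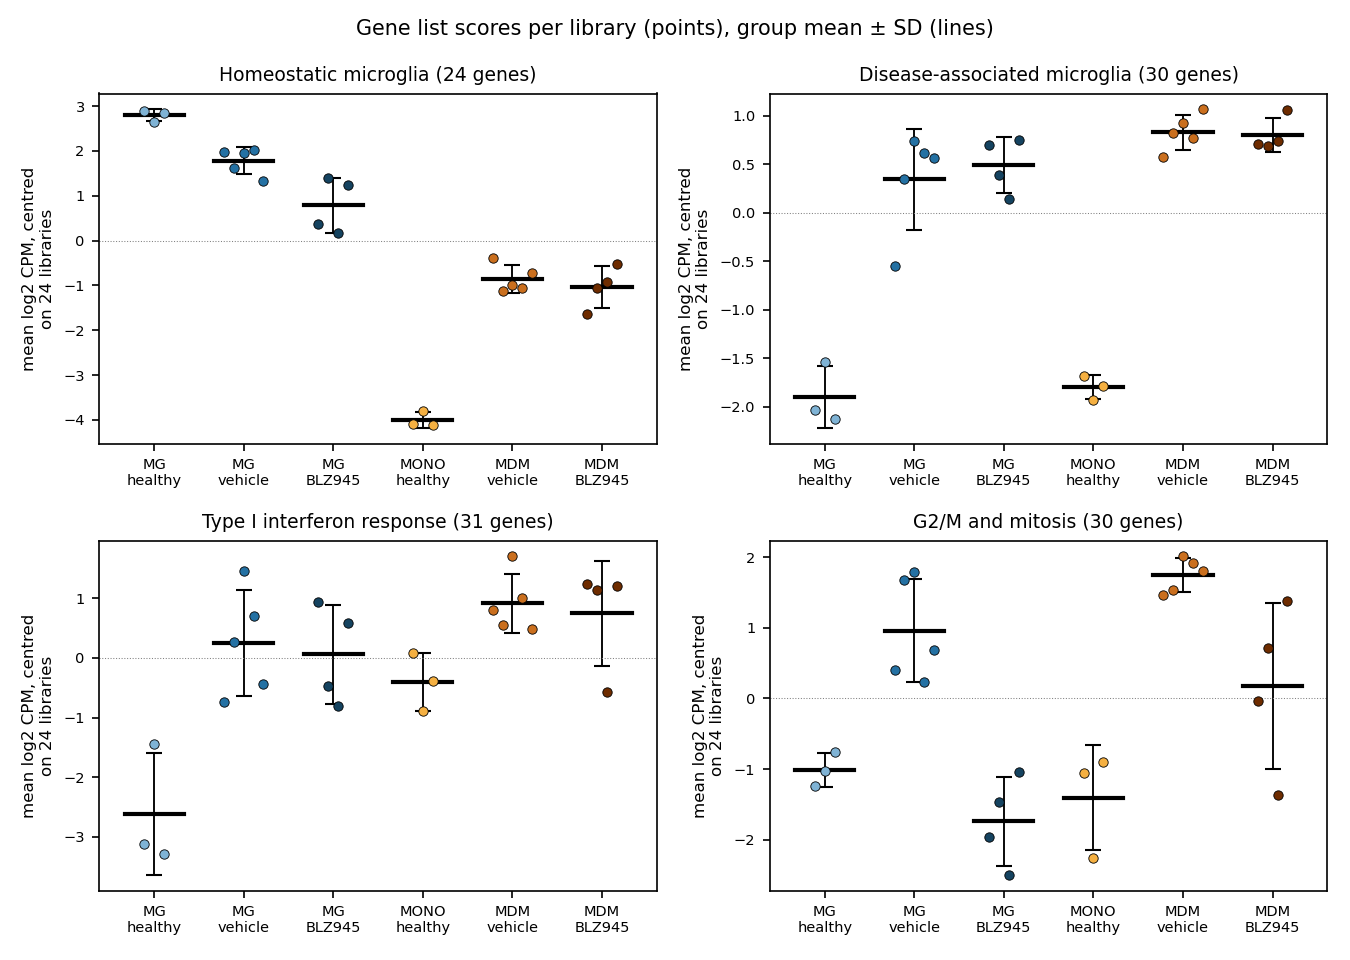
Scores of 4 gene lists (mean log2 CPM of the members, each centred on its mean over the 24 mouse libraries) in the 6 mouse groups, with a point per library and lines for the group mean ± SD. In MG the G2/M score was 0.959 ± 0.729 with vehicle and -1.74 ± 0.629 with BLZ, and the homeostatic score was 2.8 ± 0.127 in health, 1.78 ± 0.299 with vehicle and 0.788 ± 0.61 with BLZ.

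In MDM, 14 genes were higher and 15 lower with BLZ than with vehicle. Tspan7, a tetraspanin gene (chromosome X, 10485158 to 10596605), was at 153.9 ± 112 CPM (n = 4) against 37.55 ± 12.8 (n = 5), a log2 change of 2.03 ± 0.336 (adjusted p = 0.00943), or 1.42 without BLZ MDM 66277. Metrnl, which encodes the secreted protein meteorin-like (chromosome 11, 121701544 to 121716306), was at 122.8 ± 22.2 against 228.5 ± 24.6 CPM (-0.90 ± 0.152, adjusted p = 0.0101). The glutamate transporter gene Slc1a3 (chromosome 15, 8634124 to 8710764) rose by 1.61 ± 0.302 (adjusted p = 0.0184), with 151 CPM in BLZ MDM 66277 against 33 to 44.8 in the other 3 and a log2 change of 0.78 without that library. Slc1a3 lost the call without vehicle MDM 66276 (0.0554) or 66279 (0.0598) and with mouse as a random block (0.144), within a range of 0.000763 to 0.362. The transcriptional corepressor gene Tle1 fell by 1.21 ± 0.236 (adjusted p = 0.0263). Tle1 was not called without vehicle MDM 66273 (0.0791) or 66279 (0.0766), or BLZ MDM 66271 (0.0897), 66277 (0.0715) or 66296 (0.0572), or mouse 66277 (0.0772), within a range of 0.000756 to 0.3. Among the largest falls, and chosen after their values were seen, were Ace and S1pr5. Ace, the angiotensin-converting enzyme gene (chromosome 11, 105967945 to 105989964), was at 0.967 ± 0.915 against 33.4 ± 34.9 CPM (-5.13 ± 0.809, adjusted p = 0.00774; -5.99 without BLZ MDM 66271). It lost the call with limma voom (0.199) and with mouse as a random block (0.311), within a range of 1.02e-07 to 0.311. S1pr5, a sphingosine phosphate receptor gene, was at 0.298 ± 0.284 against 5.5 ± 5.89 CPM (-4.20 ± 0.766, adjusted p = 0.0101; 0.0506 without BLZ MDM 66296, 0.182 with limma voom and 0.276 with mouse as a random block, range 0.00243 to 0.342). Its log2 change was -4.80 without BLZ MDM 66271.

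With the compared groups alone, edgeR called 0 genes in MDM (1093 at unadjusted p under 0.05), so Tspan7 (0.3, range 1.46e-05 to 0.3), Metrnl (0.177, range 2.83e-05 to 0.177), Slc1a3 (0.362), Tle1 (0.3), Ace (0.3) and S1pr5 (0.342) were not called there. The count of 29 was 275 without vehicle MDM 66278, 19 without 66276, 15 without 66279, 98 without BLZ MDM 66270, 46 without 66277 and 53 without mouse 66277. DESeq2 called 116 genes and limma voom 160. Of 30 genes of G2/M and mitosis 1 was called over all genes, Anln, and 27 were lower adjusted over the list alone, with a median log2 change of -1.17. The list had a camera adjusted p of 2.1e-33 (adjusted p = 0.262 with an estimated correlation). Without mouse 66277, 5 were lower over the list alone. Anln, which encodes an actin-binding protein of cell division, was at 5.313 ± 3.4 against 22.72 ± 3.7 CPM (-2.10 ± 0.391, adjusted p = 0.0184; 0.0558 without vehicle MDM 66279 and 0.0588 without BLZ MDM 66271, range 0.000231 to 0.274). The NF-kB and proinflammatory cytokine list was higher by camera (adjusted p = 9.56e-06, adjusted p = 0.264 with an estimated correlation), with 0 of 25 members called over all genes and 3 adjusted over the list alone. Without mouse 66277 1 member of that list rose. Of 16 dendritic cell markers 1 rose, the lectin gene Cd209a, with 2 adjusted over the list alone (camera adjusted p = 7.07e-06, adjusted p = 0.547 with an estimated correlation). Without mouse 66277 2 rose, with 6 over the list alone. Cd209a was at 206 ± 230 against 36.71 ± 26.2 CPM (2.49 ± 0.542, adjusted p = 0.0371). That call was lost without vehicle MDM 66276 (0.106), 66279 (0.0938) or 66370 (0.0686), or BLZ MDM 66271 (0.265, with a log2 change of 1.42) or 66296 (0.0685), with DESeq2 (0.243), limma voom (0.0558) and the compared groups alone (0.481), and with mouse as a random block (0.269), within a range of 0.00354 to 0.481. Endothelial and mural cell markers moved with the G2/M genes, with 0 of 19 called, 0 adjusted over the list alone and a median of -0.489 (camera adjusted p = 0.00197, adjusted p = 0.547 with an estimated correlation), which was -1.14 without mouse 66277 (camera adjusted p = 0.000471). So did markers of border-associated macrophages, with a median of -0.491 (camera adjusted p = 0.0131, adjusted p = 0.756 with an estimated correlation, and 0.396 with the preset and a median of -0.292 without mouse 66277). Of these 15 markers 1 was called, and higher (1 adjusted over the list alone), which was Cd209a, a member of both lists.

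Csf1r in MDM was at 4688 ± 719 CPM with BLZ against 5066 ± 1220 with vehicle (-0.11 ± 0.236, adjusted p = 0.932), and Csf2rb was at 550.9 ± 25 against 411.8 ± 51.2 CPM (0.42 ± 0.131, adjusted p = 0.192). Cish, a target gene of Stat5, was at 15.5 ± 3.68 against 6.697 ± 7.16 CPM (1.21 ± 0.494, adjusted p = 0.338). Vehicle MDM 66278 held 19.4 CPM of Cish and the other 4 vehicle libraries 2.6 to 5, and without that library Cish passed with a log2 change of 2.13 (0.00692; 0.0238 with limma voom and all libraries, range 0.00692 to 0.577). Mouse Csf2 was below the filter on low counts, at 0.5966 ± 1.33 CPM in vehicle MDM and 0.4999 ± 0.892 in BLZ MDM. Each mean rested on 1 library. Vehicle MDM 66278 held 2.98 CPM and the other 4 vehicle libraries 0, and BLZ MDM 66277 held 1.83 CPM and the other 3 BLZ libraries 0 to 0.167.

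Whether BLZ acted differently in MDM and MG was tested as an interaction. Mki67 had the smallest adjusted p, with an effect higher by 3.00 ± 0.589 log2 units in MDM than in MG (adjusted p = 0.238; 0.00189 with DESeq2, range 0.00189 to 0.82). For Ube2c the difference was 3.54 ± 0.866 (adjusted p = 0.453; 0.0222 with DESeq2, range 0.0222 to 0.878). EdgeR called 0 genes (763 at unadjusted p under 0.05), DESeq2 14 and limma voom 1. Over the list alone 6 of 30 G2/M genes were higher in the interaction (camera adjusted p = 2.34e-09, adjusted p = 0.873 with an estimated correlation). Without mouse 66277, 13 were higher over the list alone (camera adjusted p = 5.55e-14, adjusted p = 0.856 with an estimated correlation). Dendritic cell markers had a median of 1.17 in the interaction, with 0 of 16 called and 0 adjusted over the list alone (camera adjusted p = 0.00898, adjusted p = 0.873 with an estimated correlation). EdgeR called 1 gene without BLZ MDM 66270, 1 without BLZ MDM 66277 and 1 without mouse 66277. With mouse as a fixed block edgeR called 7, and limma voom with mouse as a random block called 5. Csf1r (-0.03 ± 0.333), Csf2ra (-0.24 ± 0.277) and Csf2rb (0.27 ± 0.186) each had an adjusted p of 1.

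Across genes, which are not independent replicates, the BLZ effects in MG and MDM had a correlation of 0.282 and a covariance of 0.14. Both cell types came from the same mice, and 75 of 100 splits of the mice gave a correlation as high, with a median of 0.313 over the other splits. A covariance as high came from 19 splits. Over genes with an average log2 CPM of at least 4 the correlation was 0.413. The calls of both comparisons shared 5 genes, which are named here after their values were seen. The pseudogene Nlrp1c-ps (log2 changes 5.30 in MG and 5.57 in MDM) and Ly6g6e (1.77 and 2.45) were higher in both, against 0.028 genes in independent lists. The sorting nexin gene Snx2 (-0.55 and -0.60), the cell division gene Ect2 (-1.60 and -1.64) and the ligand gene Tnfsf8 (-1.94 and -1.89) were lower in both, against 0.108. With both cell types from the same mice, independent lists may understate the overlap that chance gives, and the overlap over splits of the mice is not given. Nlrp1c-ps was at 2.45 CPM or more in MG and MDM of BLZ mice 66270, 66271 and 66277, at 0.0556 CPM in BLZ MG 66296, and at 17.1 and 16.7 CPM in 2 of the 3 healthy MG libraries.

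Each of these 5 genes lost a call without some library. In MG, Nlrp1c-ps lost it without BLZ 66270 (0.0884, with a log2 change of 4.57), and Snx2 without vehicle 66278 (0.0526) or BLZ 66271 (0.0613). Ly6g6e lost it without vehicle 66276 (0.126), 66279 (0.0765) or 66370 (0.0751), or BLZ 66270 (0.151), 66271 (0.061) or 66296 (0.0982). Ect2 lost it in MG without vehicle 66276 (0.0823) or 66278 (0.0894), or any BLZ library (0.0613 to 0.0962), and Tnfsf8 without vehicle 66278 (0.0676), or BLZ 66271 (0.0688), 66277 (0.0713) or 66296 (0.0691). Without BLZ MG 66270 the log2 change of Tnfsf8 in MG was -2.63. In MDM, Nlrp1c-ps lost it without vehicle 66273 (0.0674), 66276 (0.0554) or 66279 (0.0627), Snx2 without vehicle 66273 (0.0523), and Ly6g6e without vehicle 66276 (0.0728), 66279 (0.0598) or 66370 (0.052), or BLZ 66296 (0.0685). Ect2 lost it in MDM without vehicle 66273 (0.0674), 66279 (0.0734) or 66370 (0.0595), or BLZ 66270 (0.0589), 66277 (0.0533) or 66296 (0.0685). Tnfsf8 lost it in MDM without vehicle 66273 (0.0771), 66276 (0.0677) or 66279 (0.0782), or BLZ 66271 (0.117), 66277 (0.102) or 66296 (0.083). With mouse as a random block Nlrp1c-ps (0.72 in MG, 0.582 in MDM) and Ly6g6e (0.0841 and 0.0875) lost both calls and Ect2 the call in MG (0.169). With limma voom Nlrp1c-ps lost both calls (0.556 and 0.406) and Ect2 the call in MG (0.117). With the compared groups alone Ly6g6e (0.215 in MG, 0.11 in MDM), Snx2 (0.162 and 0.3), Ect2 (0.0764 and 0.317) and Tnfsf8 (0.187 and 0.0681) lost both calls. Without mouse 66277 Tnfsf8 lost both (0.0613 and 0.0554) and Ect2 the call in MDM (0.0554). Over all alternatives the adjusted p reached 0.72 in MG and 0.582 in MDM for Nlrp1c-ps, 0.215 and 0.11 for Ly6g6e, 0.162 and 0.3 for Snx2, 0.169 and 0.317 for Ect2, and 0.187 and 0.117 for Tnfsf8.

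Whether BLZ brought MG back toward health was asked by setting its effect beside that of metastasis. Of the 1222 genes higher with metastasis 60 fell with BLZ, against 8.8 in independent lists, and of the 829 lower genes 3 rose, against 1.66. Across genes, the effects had a correlation of -0.171 and a covariance of -0.129. Both comparisons share the vehicle libraries. Unchanged groups simulated around these gave means of -0.0527 and -0.0102, but leave out the error that sharing adds. With the 5 vehicle libraries split 3 and 2, the means were 0.0281 and 0.0272, showing no reversal across genes. These splits called fewer genes, on average 849 higher with metastasis and 53.2 lower with BLZ. On average 15.8 were in both sets, against 2.84 in independent lists. Over genes with an average log2 CPM of at least 4 the correlation was 0.0408.

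BLZ MG compared with healthy MG had 1484 genes higher and 1167 lower. The acute-phase gene Saa3 rose by 7.06 ± 1.24 on the log2 scale (adjusted p = 0.000465), C4b by 7.04 ± 1.26 and Msr1 by 6.48 ± 0.578. The change of Saa3 was 7.82 without healthy MG 66943, and that of C4b 9.02 without healthy MG 66942 and 6.44 without BLZ MG 66270. Slc2a5 was at 4.703 ± 3.89 against 250.3 ± 88 CPM (-5.72 ± 0.668, adjusted p = 1.43e-06). Of the 24 homeostatic genes 18 fell (20 adjusted over the list alone; camera adjusted p = 7.87e-16, adjusted p = 0.0331 with an estimated correlation). P2ry12 fell by 3.15 ± 0.342 and Tmem119 fell by 1.96 ± 0.408 on the log2 scale. Genes of disease-associated microglia rose (23 of 30, 26 adjusted over the list alone; camera adjusted p = 1.02e-18, adjusted p = 0.0154 with an estimated correlation), with Apoe up by 5.88 ± 0.623. Lysosome genes rose (17 of 30, 21 adjusted over the list alone; camera adjusted p = 1.99e-12, adjusted p = 0.0213 with an estimated correlation), with the protease gene Ctsb up by 1.86 ± 0.244. Markers of border-associated macrophages were higher with them (4 of 15, 7 adjusted over the list alone; camera adjusted p = 0.0157, adjusted p = 0.531 with an estimated correlation), and 8 were called without mouse 66277. Of 23 dissociation and immediate early genes 4 were lower (1 adjusted over the list alone; camera adjusted p = 0.0157, adjusted p = 0.531 with an estimated correlation), with 5 lower over the list alone without mouse 66277. Csf2ra (1.68 ± 0.235, adjusted p = 3.72e-05) and Csf2rb (1.82 ± 0.158, adjusted p = 1.6e-07) rose. The count of 2651 was 1513 without healthy MG 66941, 1578 without healthy MG 66943, 1670 with the compared groups alone and 3260 without mouse 66277. Without that mouse, the homeostatic, disease-associated and lysosome lists were not called with an estimated correlation, at adjusted p-values of 0.0776, 0.0568 and 0.0568.

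MDM and MG of the same brains were compared within each treatment. With vehicle, MDM expressed the phospholipase-like gene Plbd1 (chromosome 6, 136612070 to 136661928) at 419 ± 182 against 4.836 ± 4.05 CPM in MG (6.46 ± 0.611, adjusted p = 9.22e-08). The chemokine receptor gene Ccr2 (chromosome 9, 124101950 to 124113557) was at 336.3 ± 153 against 4.543 ± 2.35 CPM (6.22 ± 0.638, adjusted p = 2.69e-07). The microglial transcription factor gene Sall1 (chromosome 8, 89027235 to 89044162) was lower in MDM, at 7.852 ± 3.05 against 174.3 ± 57.4 CPM (-4.47 ± 0.319, adjusted p = 1.52e-09). Csf1r was also lower (-1.20 ± 0.225, adjusted p = 0.000348). Csf1, the gene of its ligand (chromosome 3, 107741048 to 107760469), was at 29.05 ± 14.8 against 230.1 ± 99 CPM (-2.98 ± 0.518, adjusted p = 0.000163). In all, 1975 genes were higher and 1686 lower in MDM, 3661 together, and 5588 were called with mouse as a fixed block. Csf2ra was at 290.7 ± 52.3 against 216.6 ± 28 CPM (0.42 ± 0.185, adjusted p = 0.0964). It passed with mouse as a fixed block (0.00613), with mouse as a random block (0.0182) and without vehicle MDM 66276 (0.0472), within a range of 0.00613 to 0.224.

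Of the 24 homeostatic genes 22 were lower in vehicle MDM, among them P2ry12 (-3.25 ± 0.298; 22 adjusted over the list alone; camera adjusted p = 2.83e-20, adjusted p = 0.0431 with an estimated correlation). Of 20 circulating monocyte markers 18 were higher (19 adjusted over the list alone). The camera adjusted p was 1.33e-10 (adjusted p = 0.0692 with an estimated correlation). Markers of border-associated macrophages were higher too, with 14 of 15 called (14 adjusted over the list alone; camera adjusted p = 3.58e-12, adjusted p = 0.0431 with an estimated correlation), such as Cd163 (7.35 ± 0.692, or 8.44 without vehicle MG 66276 and 6.66 without vehicle MDM 66276). T and NK cell markers moved with these groups, with 9 of 15 higher in MDM (15 adjusted over the list alone; camera adjusted p = 0.0306, adjusted p = 0.637 with an estimated correlation). So did 7 of 10 B and plasma cell markers (7 adjusted over the list alone; camera adjusted p = 0.0306, adjusted p = 0.556 with an estimated correlation). Of 16 dendritic cell markers 10 were higher and 1 lower (11 and 1 adjusted over the list alone; camera adjusted p = 0.0323, adjusted p = 0.61 with an estimated correlation).

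With BLZ, 1552 genes were higher and 1209 lower in MDM than in MG. The chemokine receptor gene Ccr7 (chromosome 11, 99144196 to 99155077) was at 519.6 ± 276 against 0.8876 ± 0.331 CPM (9.19 ± 1.16, adjusted p = 7.65e-06). Plbd1 was at 687.5 ± 413 against 1.296 ± 0.812 CPM (9.09 ± 0.785, adjusted p = 4.36e-08) and Sall1 at 18.84 ± 5.19 against 121.8 ± 44.9 CPM (-2.69 ± 0.326, adjusted p = 4.16e-06). Of 30 G2/M genes 23 were higher in MDM (26 adjusted over the list alone; camera adjusted p = 5.02e-09, adjusted p = 0.38 with an estimated correlation). Mki67 was at 28.19 ± 5.57 against 2.211 ± 1.26 CPM (3.66 ± 0.481, adjusted p = 1.21e-05). T and NK cell markers moved with them, with 9 of 15 higher (12 adjusted over the list alone; camera adjusted p = 0.000236, adjusted p = 0.428 with an estimated correlation) and 2 higher without mouse 66277. Markers of circulating monocytes (15 of 20 higher, 18 adjusted over the list alone; camera adjusted p = 1.78e-10) and of border-associated macrophages (14 of 15 higher, 14 adjusted over the list alone; camera adjusted p = 1.18e-10) were higher as well. Each had an adjusted p of 0.0764 with an estimated correlation. Of 16 dendritic cell markers 8 were higher and 1 lower (11 and 1 adjusted over the list alone; camera adjusted p = 7.93e-05, adjusted p = 0.325 with an estimated correlation). Of 10 B and plasma cell markers 3 were higher (7 adjusted over the list alone; camera adjusted p = 0.0219, adjusted p = 0.5 with an estimated correlation), and 1 without mouse 66277. The count of 2761 was 2856 without mouse 66277, 1145 with the compared groups alone and 4761 with mouse as a fixed block.

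In the Csf2 receptor and Stat5 axis 5 of 24 genes were higher in BLZ MDM than in BLZ MG (5 adjusted over the list alone) and 3 without mouse 66277. Camera gave an adjusted p of 0.00281 for the axis (adjusted p = 0.243 with an estimated correlation). The kinase gene Jak2 (chromosome 19, 29251828 to 29313080) was at 223.5 ± 67.2 against 74.5 ± 19.2 CPM (1.58 ± 0.313, adjusted p = 0.00105). Stat5a (chromosome 11, 100859351 to 100885169) rose by 0.94 ± 0.223 (adjusted p = 0.00472). The cyclin gene Ccnd2 (2.31 ± 0.552, adjusted p = 0.00512) lost the call with the compared groups alone (0.0657, range 6.37e-05 to 0.0657), and its log2 change was 3.37 without BLZ MG 66270. Cish was at 15.5 ± 3.68 against 4.776 ± 3.98 CPM (1.73 ± 0.545, adjusted p = 0.0287). It lost the call without BLZ MG 66271 (0.0843), 66277 (0.0638) or 66296 (0.0791), BLZ MDM 66271 (0.0508) or 66277 (0.0622), or mouse 66277 (0.119), and with the compared groups alone (0.0891), within a range of 0.000363 to 0.119. Without BLZ MG 66270 its log2 change was 2.39. Csf2ra was at 273.6 ± 49.6 against 240.5 ± 89.6 CPM (0.19 ± 0.206, adjusted p = 0.571) and did not pass.

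Vehicle MDM were set beside the healthy MONO libraries, the other population of healthy mice. Whether MONO come from blood or brain is not stated, so this difference, and the interaction built on it, may reflect the tissue of origin as well as metastasis. Cxcl1 (chromosome 5, 90891241 to 90893115), a neutrophil chemokine gene, was at 240.4 ± 111 CPM (n = 5) against 0.2575 ± 0.255 (n = 3; 9.83 ± 0.916, adjusted p = 1.11e-08), with a log2 change of 11.04 without MONO 66942. Cxcl2 was at 778.7 ± 385 against 0.8598 ± 0.166 CPM (9.81 ± 0.805, adjusted p = 2.66e-09). S1pr5 (chromosome 9, 21242912 to 21248443) was at 5.501 ± 5.89 against 584.5 ± 35.1 CPM (-6.72 ± 0.547, adjusted p = 9.43e-11). The receptor gene Treml4 (chromosome 17, 48264295 to 48275360) was at 25.14 ± 23.9 against 1525 ± 174 CPM (-5.92 ± 0.64, adjusted p = 1.48e-07). Of 23 dissociation and immediate early genes 20 were higher in MDM, led by Fosb (8.46 ± 0.561; 20 adjusted over the list alone; camera adjusted p = 1.03e-07, adjusted p = 0.185 with an estimated correlation). Of 24 homeostatic microglia genes 19 were higher (20 adjusted over the list alone; camera adjusted p = 5.99e-05, adjusted p = 0.311 with an estimated correlation). Tmem119 was at 609.9 ± 215 against 4.729 ± 0.415 CPM, a log2 change of 7.01. Astrocyte markers were higher with them (13 of 15 higher and 1 lower, 13 and 1 adjusted over the list alone; camera adjusted p = 0.00147, adjusted p = 0.421 with an estimated correlation). Gfap among them was at 34.34 ± 8.55 against 0.03562 ± 0.0309 CPM. B and plasma cell markers were lower, with 9 of 10 called (9 adjusted over the list alone; camera adjusted p = 1.6e-06, adjusted p = 0.185 with an estimated correlation). Circulating monocyte markers were lower too (14 of 20 lower and 1 higher, 14 and 1 adjusted over the list alone; camera adjusted p = 2.13e-06, adjusted p = 0.185 with an estimated correlation), as were T and NK cell markers (10 of 15 lower and 2 higher, 10 and 3 adjusted over the list alone; camera adjusted p = 0.000844, adjusted p = 0.455 with an estimated correlation). Neuron markers (12 of 14 higher and 1 lower, 13 and 1 adjusted over the list alone; camera adjusted p = 0.00157, adjusted p = 0.285 with an estimated correlation) and border-associated macrophage markers (12 of 15 higher, 12 adjusted over the list alone; camera adjusted p = 6.52e-05, adjusted p = 0.225 with an estimated correlation) were higher. Csf2ra was lower in MDM (-0.64 ± 0.21, adjusted p = 0.0144). This call was lost without MONO 66942 (0.105) or 66943 (0.0589) or vehicle MDM 66276 (0.0696), within a range of 0.00384 to 0.105. Csf1r did not pass (0.54 ± 0.261, adjusted p = 0.091). It passed with DESeq2 (0.014), with limma voom (0.00885), with no filter on low counts (0.0413), with mouse as a random block (0.0489) and without vehicle MDM 66278 (0.0212), within a range of 0.00885 to 0.192. Csf2rb did not pass either (0.34 ± 0.144, adjusted p = 0.0567), except with DESeq2 (0.038) or without vehicle MDM 66273 (0.028) or 66279 (0.0175), within a range of 0.0175 to 0.159. In total 3986 genes were higher and 3130 lower.

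In healthy mice, MONO had 3799 genes higher and 4278 lower than MG. S1pr5 (9.81 ± 0.824, adjusted p = 8.11e-11) and the protease gene Napsa (9.65 ± 0.744) were higher. So was Gzma, which encodes a granzyme of T and NK cells, at 558.9 ± 362 against 0.8022 ± 0.201 CPM (n = 3 each; 9.44 ± 1.67, adjusted p = 4.88e-05), with a log2 change of 8.75 without MONO 66941. Siglech was lower, at 1.393 ± 0.26 against 1465 ± 76.6 CPM (-10.03 ± 1.07, adjusted p = 7.16e-08), as was Csf1r, at 3494 ± 149 against 13960 ± 1330 CPM (adjusted p = 6.65e-06). Csf2ra was higher in MONO, at 453.8 ± 69.4 against 75.28 ± 3.77 CPM (adjusted p = 1.81e-08), and so was Csf2rb, at 326.2 ± 45.1 against 140.4 ± 21.8 CPM (adjusted p = 1.58e-06). All 24 homeostatic genes were lower (24 adjusted over the list alone; camera adjusted p = 1.28e-12, adjusted p = 0.18 with an estimated correlation). All 20 circulating monocyte markers were higher (20 adjusted over the list alone; camera adjusted p = 1.13e-08, adjusted p = 0.18 with an estimated correlation). B and plasma cell markers, with 10 of 10 higher, moved with them (10 adjusted over the list alone; camera adjusted p = 7.27e-05, adjusted p = 0.47 with an estimated correlation). So did T and NK cell markers, with 10 of 15 higher (11 adjusted over the list alone; camera adjusted p = 0.00174, adjusted p = 0.711 with an estimated correlation). Astrocyte markers (13 of 15 lower, 13 adjusted over the list alone; camera adjusted p = 0.00322) and neuron markers (11 of 14 lower and 1 higher, 11 and 1 adjusted over the list alone; camera adjusted p = 0.0078) were lower in MONO, each with an adjusted p of 0.711 with an estimated correlation. Of 23 dissociation and immediate early genes 20 were lower and 1 higher (20 and 1 adjusted over the list alone; camera adjusted p = 1.01e-08, adjusted p = 0.18 with an estimated correlation).

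The difference between vehicle MDM and MONO was then compared with that between vehicle and healthy MG in 1 interaction test. The integrin gene Itga9 had the largest positive difference among the genes named by the rule (9.79 ± 0.932, adjusted p = 6.94e-08, or 11.51 without MONO 66942), followed by the scavenger receptor gene Stab1 (9.34 ± 0.545). Cd244 had the largest negative one (-8.12 ± 0.528, adjusted p = 2.54e-10). Csf2ra (-2.17 ± 0.306, adjusted p = 1.26e-05) and Csf2rb (-1.33 ± 0.203, adjusted p = 3.35e-05) were lower in this test and Csf2rb2 higher (1.13 ± 0.238, adjusted p = 0.000925). In total 2595 genes had a more positive and 1929 a more negative change in MDM. Calls higher in both comparisons numbered 621, against 347 in independent lists, and calls lower in both 249, against 185. Both comparisons used the same mice, so independent lists are not the value to expect without a shared effect, and no such value is given. Among markers of other cell types 12 of 15 for astrocytes (12 adjusted over the list alone; camera adjusted p = 0.000881) and 10 of 14 for neurons (10 adjusted over the list alone; camera adjusted p = 0.00115) had a more positive change in MDM. A more negative one was found for 10 of 20 markers of circulating monocytes (10 adjusted over the list alone; camera adjusted p = 0.000369), 4 of 10 of B and plasma cells (4 adjusted over the list alone; camera adjusted p = 0.00121) and 1 of 15 of T and NK cells (1 adjusted over the list alone; camera adjusted p = 0.0194). With an estimated correlation these 5 lists had adjusted p-values of 0.589 to 0.754.

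In the human tumor cells, edgeR called 0 of 14007 genes between BLZ (n = 4) and vehicle (n = 5), with 1551 at unadjusted p under 0.05. DESeq2 called 240 genes and limma voom 195. TOP2A, which encodes a topoisomerase of dividing cells, was at 169.2 ± 22.6 against 341.9 ± 111 CPM (-1.01 ± 0.231, adjusted p = 0.162). It passed with DESeq2 (0.00504), with limma voom (0.0355) and without vehicle tumor 66273 (0.0156), within a range of 0.00504 to 0.465. MKI67 was at 102.8 ± 9.84 against 179.4 ± 51.1 CPM (-0.80 ± 0.194, adjusted p = 0.169; 0.014 with DESeq2, 0.0359 with limma voom and 0.0196 without vehicle tumor 66273, range 0.014 to 0.465). The 30 G2/M genes had a median log2 change of -0.643, with 0 called over all genes and 24 lower adjusted over the list alone (camera adjusted p = 6.07e-18, adjusted p = 0.449 with an estimated correlation). Among 30 DNA repair genes 0 were called and 10 were lower adjusted over the list alone (camera adjusted p = 4.26e-06, adjusted p = 0.449 with an estimated correlation). Exact permutation tests of the scores over 126 splits of the mice did not pass for G2/M (p = 0.0556, adjusted p = 0.0741 over 12 tests) or for G1/S and DNA repair (each p = 0.0317, adjusted p = 0.0634). Endothelial and mural cell markers moved the same way as the G2/M genes, with 0 of 11 called, 0 adjusted over the list alone and a median of -0.395. Their camera adjusted p of 0.00505 (adjusted p = 0.449 with an estimated correlation) was 0.423 without mouse 66277.

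The genes of the myeloid growth factors did not pass the test in tumor cells. CSF1 was at 71.61 ± 6.76 CPM with BLZ against 72.23 ± 22.7 with vehicle (-0.01 ± 0.189, adjusted p = 0.984) and CSF2 at 6.959 ± 3.37 against 8.846 ± 2.72 CPM (-0.33 ± 0.328, adjusted p = 0.766). CSF3 was at 11.42 ± 10.2 against 6.485 ± 1.66 CPM (0.79 ± 0.44, adjusted p = 0.544), with 26.6 CPM in BLZ tumor 66277 and 4.59 to 7.44 in the other 3 BLZ libraries. IL34 was below the filter on low counts, at 0.0891 ± 0.0848 against 0.509 ± 0.236 CPM. Without vehicle tumor 66273 edgeR called 86 genes, without BLZ tumor 66277 21, without mouse 66277 21, and with no filter on low counts 13.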

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

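The rule for a library apart from its group and the test of the interaction were set in advance, and the fits without mouse 66277 were chosen after results were seen. The rule was applied to the lists and gene levels that the text gives, some of them chosen after their values were seen. In 16 of 220 groups of 4 or 5 libraries (6 of library totals, 108 of list scores, 106 of levels of the named genes), the highest or lowest library lay apart from the others by more than Dixon's limit. Chance sets a library apart in about 1 in 20 groups that are fixed in advance, which not all of these were.

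The total of BLZ MG 66270 was 15.8 M counts, against 18.6 to 19.1 M in the other 3 BLZ MG libraries. The score of disease-associated microglia was 1.06 in BLZ MDM 66296, against 0.691 to 0.745 in the others of its group. The interferon score was -0.572 in BLZ MDM 66277, against 1.13 to 1.23. The lipid uptake and efflux score was -0.863 in vehicle MG 66273, against -0.0107 to 0.261. In vehicle MG 66278 the score of T and NK cell markers was 0.708, against -2.44 to -1.66. In BLZ MDM 66270 the score of B and plasma cell markers was 1.14, against -0.165 to -0.0438. The interferon score was 0.453 in vehicle tumor 66278, against -0.18 to -0.00494, and the cholesterol synthesis score 0.315 in BLZ tumor 66296, against -0.0948 to -0.0478.

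Vehicle MDM 66278 lay apart from its group in 5 values. Its dissociation and immediate early gene score was -0.427, against 0.0692 to 0.265. It held 15 CPM of Adamdec1 against 0.97 to 4.13, 19.4 CPM of Cish against 2.6 to 5, 154 CPM of Itga4 against 83.2 to 92, and 2.98 CPM of Csf2 against 0. Adamdec1, chosen after its values were seen, was lower in MDM under BLZ (log2 change -3.79 ± 0.825, adjusted p = 0.0392). It was not called without vehicle MDM 66278 (0.0538, with a log2 change of -2.58) or 66279 (0.0649), BLZ MDM 66271 (0.0897), 66277 (0.0906) or 66296 (0.102), or mouse 66277 (0.0851), with DESeq2 (0.196), with limma voom (0.143), with the compared groups alone (0.416) or with mouse as a random block (0.17), within a range of 0.0176 to 0.416. Without BLZ MDM 66270 its log2 change was -4.98. Among the libraries of mouse 66277, BLZ MDM held 151 CPM of Slc1a3 against 33 to 44.8 in the others and 1.83 CPM of Csf2 against 0 to 0.167, and BLZ tumor 26.6 CPM of CSF3 against 4.59 to 7.44.

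A difference between cell types was also found by its own test. The change between MDM of mice with metastases and MONO differed from the change between vehicle and healthy MG for 4524 genes, 2595 more positive and 1929 more negative in MDM. Lists in this test included homeostatic microglia, with 21 of 24 genes more positive in MDM (24 adjusted over the list alone; camera adjusted p = 3.18e-10, adjusted p = 0.276 with an estimated correlation). Itga9 had a difference of 9.79 ± 0.932 log2 units.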

How the results depend on the processing

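Fits without mouse 66277 and with exchanged MONO numbers were chosen after seeing the data. The others were chosen in advance, and all of them ran. Of 158 named gene results that were called, 35 lost the call under at least 1 alternative (159 of 2492 alternatives) and 0 reversed. Of 648 alternatives on the 39 results not called, 62 made a call. Another scaling changed no count of genes by over 1.5 times. The cause of the following changes was not tested.

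Limma voom called 4157 genes in vehicle against healthy MG, 44 in MG under BLZ, 160 in MDM under BLZ, 1 in the BLZ interaction and 195 in tumor cells. DESeq2 called 313, 116, 14 and 240 in the last 4 of these. With the compared groups alone, which leaves fewer libraries to estimate the spread, the counts were 25 for MG under BLZ, 0 for MDM under BLZ (edgeR, 1093 at unadjusted p under 0.05), 1670 for BLZ against healthy MG and 1145 for MDM against MG with BLZ. Without a filter on low counts 13 genes were called in tumor cells. With mouse as a fixed replicate block the counts were 5588 for MDM against MG with vehicle, 4761 with BLZ and 7 for the BLZ interaction. With mouse as a random replicate block, fitted in limma voom rather than edgeR, they were 54 for MG under BLZ, 4.5e3 for MDM against MG with BLZ and 5 for the interaction. The blocks moved no other count of genes by over 1.5 times and, among the genes and lists the text names, changed no call other than those given beside the results. With the numbers of MONO 66941 and 66942 exchanged, the fixed block called 9431 genes in MONO against MG (9318 as labelled). Without mouse 66277, 53 genes were called in MDM under BLZ, 1 in the interaction and 21 in tumor cells.

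Leaving out 1 library at a time gave 1080 to 2308 genes for vehicle against healthy MG, 67 to 174 for MG under BLZ, 15 to 275 for MDM under BLZ, 1513 to 2837 for BLZ against healthy MG, 0 to 1 for the BLZ interaction and 0 to 86 for tumor cells. In the other comparisons every such count stayed within 1.5 times. Of 144 list calls among 342 tests, 10 were called with an estimated correlation and 89 were kept with fry. Without mouse 66277, 55 of 66 were kept with the preset and 0 called with an estimated correlation. Oxidative phosphorylation in MDM under BLZ reversed there, at adjusted p = 0.88 and, with an estimated correlation, 0.973. With the fixed replicate block 64 of 67 list calls were kept. The correlation of the BLZ and metastasis effects in MG reversed to 0.0281 with the vehicle libraries split and to 0.0408 over genes with an average log2 CPM of at least 4. The correlation of the BLZ effects in MG and MDM was 0.413 over such genes. Mouse Csf2 and human IL34 fell below the filter on low counts, and whether depth or low expression is the reason was not tested.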

Other observations

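The permutation tests, the tests of explanations and the counts of splits in this part were chosen only after the results were seen, and so were the list tests without mouse 66277. The other list tests were not. Genes of cholesterol synthesis were higher with BLZ by camera in both cell types. In MG 1 of 23 rose, Msmo1 (4 adjusted over the list alone), with a list median of 0.275 log2 units (camera adjusted p = 0.00119, adjusted p = 0.581 with an estimated correlation). Msmo1, a sterol oxidase gene (chromosome 8, 64718139 to 64733792), was at 52.05 ± 9.13 against 35.67 ± 3.05 CPM (0.54 ± 0.128, adjusted p = 0.0396). It lost the call without vehicle MG 66276 (0.109), 66278 (0.0888) or 66370 (0.0814), or BLZ MG 66270 (0.16), 66277 (0.0633) or 66296 (0.0508), with limma voom (0.0828), with no filter on low counts (0.0852), with the compared groups alone (0.208) and with mouse as a random block (0.105), within a range of 0.00656 to 0.208. In MDM 0 of 23 were called (0 adjusted over the list alone), with a median of 0.329 (camera adjusted p = 0.000345, adjusted p = 0.547 with an estimated correlation). Without mouse 66277, 2 of 23 rose in MG (5 adjusted over the list alone), and in MDM 0 were called and 2 were higher over the list alone.

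In vehicle against healthy MG, 15 of 30 genes of oxidative phosphorylation were higher (18 adjusted over the list alone; camera adjusted p = 1.99e-09, adjusted p = 0.312 with an estimated correlation), as were 10 of 16 complement genes (11 adjusted over the list alone; camera adjusted p = 2.49e-07, adjusted p = 0.0561 with an estimated correlation). In MDM under BLZ, 0 of 15 T and NK cell markers were called (0 adjusted over the list alone), with a median of 0.641 (camera adjusted p = 0.0112, adjusted p = 0.791 with an estimated correlation). Without mouse 66277 that median was -1.64 and the camera adjusted p 0.446.

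The G2/M genes were lower in MG under BLZ, with a score of -1.74 ± 0.629 in 4 libraries against 0.959 ± 0.729 in 5 (exact two-sided permutation p = 0.00794, the smallest possible with 126 splits; adjusted p = 0.0238 over 12 tests), and every BLZ library was below every vehicle library. Fewer MDM cells in the MG gate would need MG to hold monocyte and macrophage markers at the level of G2/M genes. Of these markers, 32 were called higher in vehicle MDM than in vehicle MG, including Itga4, the gene of the sorting antigen Cd49d. They stood at a median of 4.05% of their MDM level in vehicle MG (range 0 to 55), and G2/M genes at 61.9%. Only the markers were chosen by such a call, which lowers their percent, though most markers of both lists passed it. The markers had a median log2 change of -0.375 in MG under BLZ, with 0 called, which is the direction that fewer MDM cells would give, so the levels argue against this source for most of the fall and leave a small part open. That 1 mouse decides the fall was also argued against, since without any 1 MG library or without mouse 66277 at least 14 G2/M genes were called lower, against 25 with all libraries. The G1/S score differed by -0.449 (exact permutation p = 0.333, adjusted p = 0.333). The G2/M minus G1/S score, in which a scaling factor per library cancels, differed by -2.25 (exact permutation p = 0.00794, adjusted p = 0.0238), which argues against the scaling between libraries. In MDM the G2/M score was lower with BLZ as well, with a difference of -1.58 (exact permutation p = 0.00794, adjusted p = 0.0238), and the G2/M minus G1/S score differed by -0.946 (exact permutation p = 0.0476, adjusted p = 0.0714). Between MDM and MG of the same mice the BLZ difference of the G2/M score differed by 1.12 (exact permutation p = 0.0397, adjusted p = 0.0681) and did not pass, and that of the G2/M minus G1/S score by 1.3 (exact permutation p = 0.00794, adjusted p = 0.0238). A response of MG to BLZ stays open, as no test of it apart from the comparison itself was made.

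Ace, S1pr5 and Adamdec1 were lower in MDM under BLZ and stood at 1520 ± 106, 584.5 ± 35.1 and 112 ± 33.4 CPM in MONO. If MDM gates held fewer cells like those of the MONO libraries under BLZ, other genes high in MONO would fall as well. Over 57 such genes, at least 32-fold higher in MONO than in MG and 16-fold higher than in MDM, the median change was -0.581 (quartiles -1.34 and 0.142), 42 were negative and 0 were called, 17 being lower over the set alone. Treml4 was at 4.12 to 60.4 CPM in vehicle MDM and 0.802 to 8.02 in BLZ MDM, Cd300e at 3.09 to 53.6 and 1.15 to 6.36, and the score of the set did not pass (exact permutation p = 0.206, adjusted p = 0.225). In vehicle MDM the set stood at a median of 3.66% of its MONO level, against 2.2% for Ace, 0.942% for S1pr5 and 4.12% for Adamdec1, so these levels do not say whether what MDM themselves hold of the members hides the loss of a small share. This source may or may not be the cause and cannot be told apart from a change within MDM. The sort on Cd49d would keep such cells, given 581 ± 75.2 CPM of Itga4 in MONO, and that against Ly6c would remove those that carry it. MONO held 13.17 ± 11.2 CPM of Ly6c2 and 0.09149 ± 0.0619 of Ly6c1. These RNA levels, which need not follow the surface protein, do not show that this gate would remove most of them.

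In 41 genes, MG and MDM alike were on in some of the 9 tumor mice and off in others, by a gap of at least 2 log2 units, against a median of 1 and a highest of 19 over 100 shuffles of the mice. Here on and off mean only the sides of this gap. These genes include H2-Q5 (chromosome 17, 35394126 to 35397800), on in mice 66276, 66278, 66370, 66277 and 66296, and Nlrp1c-ps (chromosome 11, 71242430 to 71285232), on in 66270, 66271 and 66277. Fn1 was on the low side in 66277 alone, at 40.8 CPM in MG and 132 in MDM, against 6.56 to 8.29 in healthy MG. A response in all BLZ mice is argued against, as for 0 genes were the mice on all and only BLZ or vehicle mice. A response in some stays open. A variant carried by some mice is a candidate explanation for some of these genes: of 24 gene pairs with the same mice on, 16.7% lay on 1 chromosome, against 8.23% of other pairs. Those on 1 chromosome were the pairs among D17H6S53E, H2-Q5 and Gm11127 (chromosome 17, 35126373 to 36058371) and Kcnj14 with Tnfrsf26 (chromosome 7). The difference thus rests mostly on 1 stretch of chromosome 17. Fn1, Kif18b, Tmem14c, Ndc80 and Pilra, on in all tumor mice but 66277, each lay on a different chromosome. Of 39 such genes with a position 10 lay on chromosome 17 and 6 within 10 Mb of each other, and 2 of 1000 random draws of 39 genes had as many within 10 Mb. In healthy mice, 16 of 19 such genes matched between MG and MONO with the numbers of MONO 66941 and 66942 exchanged, 4 as labelled and 9 at most in the other 4 pairings. H2-Q5 was on in MG 66942 and MONO 66941 alone, and Nlrp1c-ps was off in MG 66941 and MONO 66942 alone. When the MONO mice were reassigned at random chromosome by chromosome, 0 of 1000 draws had 16 matches under any pairing (highest 15, median 9). An exchange of these 2 numbers between MG and MONO is therefore a candidate explanation, and the values do not say in which cell type. Of the calls under BLZ, 3 of 129 in MG and 1 of 29 in MDM are genes of this kind.

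Other splits of the same libraries or mice were refitted. In vehicle against healthy MG 1 of 56 splits, the real one, called 2051 genes or more (highest other 664), in MDM against MONO 1 of 56 called 7116 (1989), in BLZ against healthy MG 1 of 35 called 2651 (1833), and in the metastasis interaction 1 of 56 called 4524 (0), so chance was excluded at this level. In MDM against MG with vehicle 1 of 100 splits called 3661 genes (highest other 502), and the 10 others that part all 5 pairs of libraries called at most 2. With BLZ 1 of 35 called 2761 (2304), the highest other parting fewer pairs, and the 7 others that part all 4 pairs called at most 275. The paired counts with a fixed replicate block were 5588 and 4761. In MG under BLZ 2 of 100 splits called 129 genes or more. The highest other called 462, several times the real count, and sets mice 66276, 66370, 66277 and 66296 against the rest, which points to a structure of the samples other than treatment. These 4 are among the 5 mice with H2-Q5 on.

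In MDM under BLZ 22 of 100 splits called 29 genes or more, so chance was not excluded. The highest other called 343 and differs from the real split only in setting vehicle mouse 66278 with the BLZ mice. Without vehicle MDM 66278 the real groups gave 275 calls. This split therefore does not tell a structure of the samples from a treatment effect with 1 deviating vehicle mouse. In the BLZ interaction the real split called 0 genes (edgeR, 763 at unadjusted p under 0.05, DESeq2 14, limma voom 1) and the highest other 3. In tumor cells the real split also called 0 (edgeR, 1551 at unadjusted p under 0.05, DESeq2 240, limma voom 195). The highest other called 105 and differs from the real split only in setting vehicle mouse 66273 with the BLZ mice. Without vehicle tumor 66273 the real groups gave 86 calls, so this split cannot tell these 2 apart either. All 100 splits call at least 0 genes by definition, so for these 2 comparisons the count of splits tests nothing. For MONO against MG the 10 splits are too few for a share under 0.05. The real one called 8077 genes and the highest other 3.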
